A study of Caenorhabditis elegans with 6 samples.

How the data were processed

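Libraries came from 6 samples of *C. elegans* strain PY2417, 3 from animals fed *E. coli* OP50 and 3 from animals fed a *Methylobacterium* (treatment Methylobacterium/Red, sample titles Red), all labelled as AWB and AWC neurons. The treatment text names cells sorted for red fluorescence, the extraction text homogenised worms, and the growth text wild-type and *odr-1* loss-of-function worms. The authors deposited 1 table of whole-number read counts per gene, with a column per sample, and columns were matched to samples by title. Per the submitters' processing notes, the tools used were CASAVA 1.8, Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and DESeq2 1.18.0 with genome build ce11. The notes list them without role or order. The gene annotation, the strand setting of the counting and the read length were not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies, such as the major sperm protein, histone and collagen genes, cannot be assigned with certainty.

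The table held 46928 gene entries and 5 summary entries of reads given to no gene. The summary entries took 14.4%, 29.8% and 44.1% of the OP50 libraries and 22.4%, 18.1% and 17.4% of the *Methylobacterium* libraries, and were left out of library sizes and tests. Of these, reads outside any annotated gene made up 1.49%, 14.5% and 18.3% on OP50 and 3.21%, 5.56% and 2.13% on *Methylobacterium*. Gene symbols and coordinates came from the RefSeq table of assembly WBcel235, the assembly known as ce11, in which 46919 entries were matched and 9 were not. Gene counts totalled 25346981, 9810788 and 3478555 on OP50 and 20531416, 23937002 and 35078043 on *Methylobacterium*, so that a floor of 3 counts corresponds to 0.118, 0.306, 0.862, 0.146, 0.125 and 0.0855 CPM. Protein-coding genes with a count numbered 13536, 17353 and 10141 on OP50 and 7681, 8780 and 13770 on *Methylobacterium*. Ribosomal RNA took 5.87% to 17.5% of gene counts.

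Position along the genome was then checked. Among genes with at least 30 counts in at least 3 libraries, the last with at least 1 CPM was found in each library, in the order I, II, III, IV, V, X and mitochondrial genome. *Methylobacterium* replicates 1 and 3 ended before the mitochondrial genome, the other 4 libraries on it. Genes were accordingly placed in a shared stretch counted in 6 libraries (19787 genes, 11235 protein-coding), a second stretch counted in 5 (26892 genes) and a last one counted in 4 (240 genes). The shared stretch held 71.4% to 78.6% of the gene counts of the OP50 libraries.

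The comparison was *Methylobacterium* minus OP50 over all 6 libraries with edgeR 4.0.16 (R 4.3.3), using filterByExpr, TMM scaling and the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. It tested 12725 genes, with a common biological coefficient of variation of 1.53, or 1.19 on the shared stretch. Because zeros past the end of a library enter this fit as measured values, the same fit was added on the shared stretch (8397 genes), and a further one treated uncounted stretches as missing, with 6 libraries on the shared stretch and the 5 without *Methylobacterium* replicate 1 on the next. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and with an estimated correlation and fry beside it. Fry, which asks whether a list's genes move on balance one way, called 0 lists, with a lowest adjusted p of 0.205 on all genes and 0.18 on the shared stretch. The comparison and all 31 lists were fixed before the data were examined, and the lists had at least 5 tested members, 28 of them on the shared stretch. Gene classes needed at least 10 tested members. A list's share of each library's gene counts was compared by an exact two-sided permutation test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.

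Genes are named by a rule fixed in advance: the 10 largest called changes each way with a mean of at least 5 CPM and no overlap between groups, or, as happened, the 5 lowest p-values each way where none passes; up to 4 called members per response list; up to 3 of the highest members per cell type list; up to 3 members per called gene class; and a fixed set of *odr-1*, *lin-15A*, *lin-15B*, *str-1*, *str-2*, *srsx-3*, *ceh-36*, *tax-2*, *tax-4*, *odr-3*, *acdh-1*, *fat-5*, *fat-6* and *fat-7*. Fold changes between group means are of CPM scaled to the counts of the shared stretch. For genes with no counts in 1 group, the fold is a bound against 3 counts over the libraries of that group that counted the gene.

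The gene test was tested on simulated counts with these libraries' means and sizes and 200 changed genes, 50 at each fold. With a low dispersion of 0.05 (12697 genes), 60% of 2-fold changes and 100% of 4-fold, 16-fold and 64-fold changes were recovered, with 8 unchanged genes called. With the dispersion of these libraries (10786 genes), 0% were recovered at each of the 4 folds. A single gene with a 64-fold change was thus not detectable in the fit on all genes. That fit takes uncounted zeros as measured, and its biological coefficient of variation was 1.53. No simulation was run on the shared stretch, where it was 1.19, or without *Methylobacterium* replicate 1, so detection there is not known.

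Alternatives named beforehand were DESeq2 size factors, library totals and upper quartile scaling, no filter, a filter of at least 50 counts in 3 libraries, the replicate number as a block, a robust fit, DESeq2 1.42.0, each library left out in turn, the estimated correlation, and another denominator for the shares. Alternatives that used the shared stretch or treated uncounted stretches as missing were added after the data were seen. Each fit applied its filter anew, so a list's median without 1 library is not over the same genes. The fit on all genes without *Methylobacterium* replicate 3 tested 14007 genes, against 12725 with all 6 libraries. It rests on replicate 1, with its uncounted zeros, and on replicate 2, where 31% of expressed genes were under 1 CPM.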

Results

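Gene expression was measured by RNA sequencing in samples of adult *Caenorhabditis elegans* labelled as AWB and AWC neurons, 2 classes of olfactory neuron in the head. The treatment text says that cells were sorted for red fluorescence, but the extraction text describes homogenised worms, so levels and shares may be those of sorted cells or of whole animals. The strain given for all samples, PY2417, carries a transgene in which the promoter of *odr-1*, a receptor-type guanylate cyclase used in odour signalling, drives a red fluorescent protein. The growth text also names *odr-1* loss-of-function worms, so the genotype, on which the values of *odr-1* and the guanylate cyclases bear, rests on the sample labels. Animals were kept for 72 h on *E. coli* OP50, the usual laboratory food, or on a *Methylobacterium* (labelled Methylobacterium/Red, with Red not explained), and were collected on day 1 of adulthood, with 3 libraries per food. The OP50 libraries held 25346981, 9810788 and 3478555 counts in genes and the *Methylobacterium* libraries 20531416, 23937002 and 35078043. The labels do not say that the replicates came from separate cultures. The p-values of single genes measure the spread between these 6 samples, which may thus be technical. Camera's p-values set a list's genes against other genes and, at the preset correlation of 0.01, take the list's genes as nearly independent. Estimated correlations on all genes were 0.2 for the cuticle list, 0.363 for the ribosomal list and 0.924 for the mitochondrial list.

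The counts of 2 *Methylobacterium* libraries stopped partway along the genome. In replicate 1 the last gene with at least 1 CPM (counts scaled to the library's total) was *his-45* (chromosome IV, 11326588 to 11326998, WBcel235), and 3470 of 3481 expressed genes after it were at 0 counts. In replicate 3 the last such gene was *got-1.2* (chromosome X, 16791347 to 16793126), with 47 of 50 expressed genes after it at 0, among them the mitochondrial genes. Replicate 2 was counted to the end, but 3305 of 10661 expressed genes (31%) were under 1 CPM in it, against 23.7% in OP50 replicate 3 and 1.798% to 8.534% in the other libraries before any end. A value near 0 in that library alone does not show a lower level. The 19787 genes up to *his-45*, counted in all 6 libraries, are called the shared stretch here, and a zero after a library's last gene is called uncounted. Levels are given in CPM of the shared stretch, scaled to a library's counts there, as mean ± SD over the libraries that counted the gene. Shares of all gene counts take in every library, and in *Methylobacterium* replicates 1 and 3 they hold only the genes counted there. Values on the shared stretch were added after the data were seen.

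**Figure D1:**
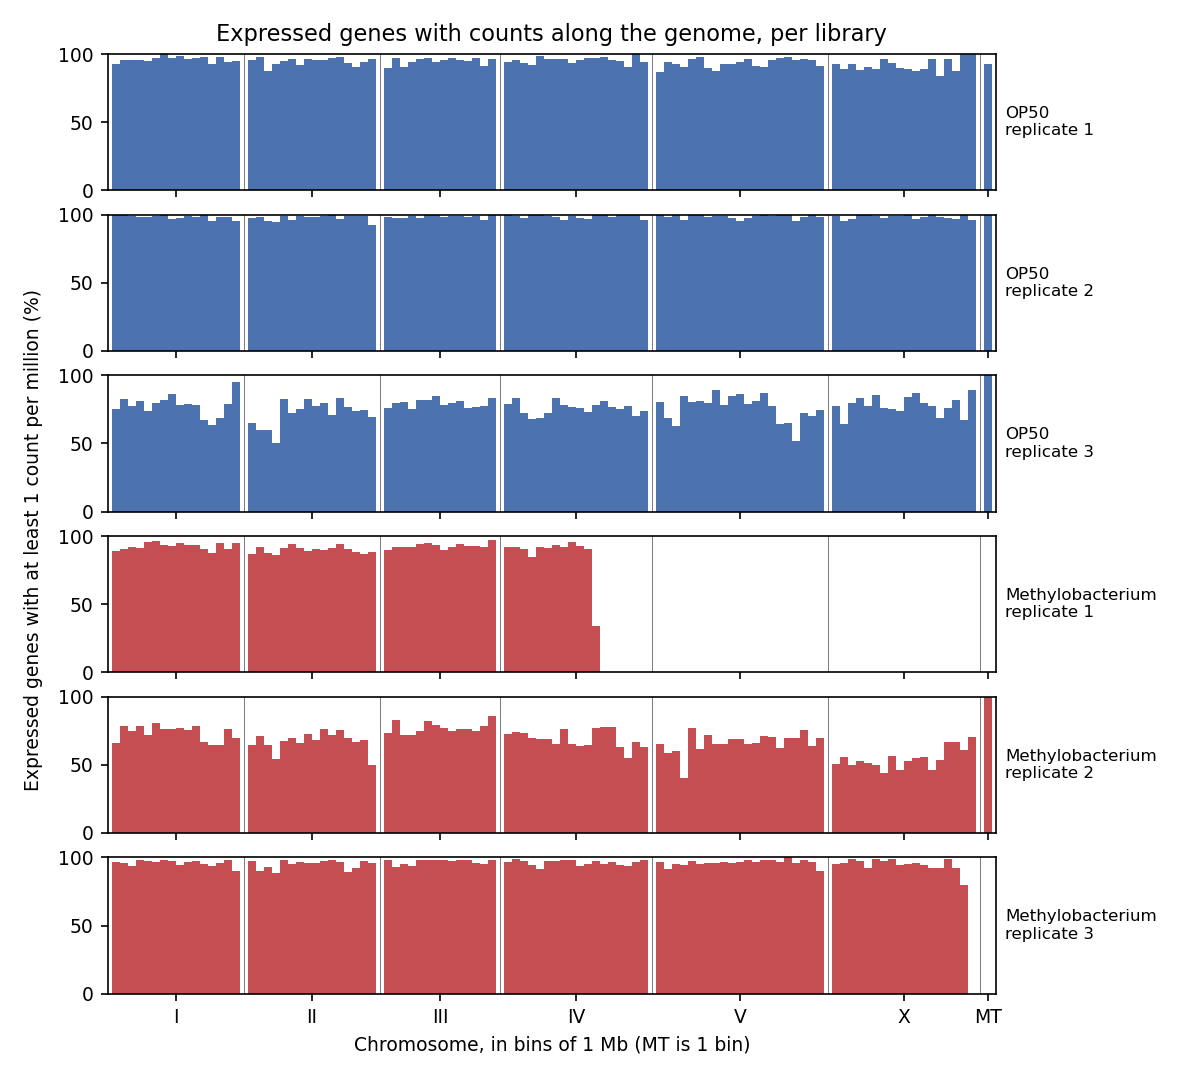
Percentage of expressed genes with at least 1 CPM in bins of 1 Mb along the chromosomes, 1 panel per library (blue, OP50; red, *Methylobacterium*; the mitochondrial genome is 1 bin). The bars of *Methylobacterium* replicate 1 end on chromosome IV, where *his-45* was its last such gene, and those of replicate 3 end on X, where *got-1.2* was the last.

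The study's comparison asked how gene expression in these neurons differs between the 2 foods. Genes of the propionate shunt, the pathway that breaks down propionate when vitamin B12 is scarce, fell as a list on *Methylobacterium*. Transcripts of *acdh-1* (CELE_C55B7.4, chromosome I, 6497436 to 6499560), the acyl-CoA dehydrogenase at the head of the shunt, were at 467 ± 555 on OP50 and 4.96 ± 7.21 on *Methylobacterium* (SD, n = 3 each), a 94.1-fold lower mean with no overlap between the libraries. The fold was 29.8 without OP50 replicate 3 and 574 without *Methylobacterium* replicate 1. The same separation held for *hphd-1* (232 ± 191 against 21.2 ± 10.8, 10.98-fold lower), *alh-8* (864 ± 393 against 194 ± 51.1, 4.46-fold lower) and *ech-6* (467 ± 319 against 120 ± 59.1, 3.91-fold lower), which encode later enzymes of the shunt. Without OP50 replicate 3 *hphd-1* was 5.95-fold and *ech-6* 2.37-fold lower. The level of *hach-1*, the hydrolase of the pathway, was 220 ± 39.1 on OP50 and 138 ± 64.6 on *Methylobacterium*, and the groups overlapped. Chance would separate 10% of genes in this way with 3 libraries against 3.

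Beside enzymes of the shunt, the fixed list holds *acdh-2*, *pmp-5* and the nuclear hormone receptor genes *nhr-10*, *nhr-68* and *nhr-114*. All 9 tested members of the shunt list had a negative log2 fold change, with a median of -3.28, and on the shared stretch all 7 did, with a median of -2.08 (camera adjusted p = 7.31e-06 and 1.08e-05). These calls were lost at adjusted p = 0.812 with an estimated correlation on all genes, and at adjusted p = 0.497 with an estimated correlation on the shared stretch. Without *Methylobacterium* replicate 3 the median on the shared stretch was -3.38. No member passed edgeR's test adjusted over all genes, while 3 of 9 passed when adjusted over the list alone, and 4 of 7 did so on the shared stretch. The log2 fold change of *acdh-1* was -6.42 (SE 1.84, unadjusted p = 0.00914), and on the shared stretch -6.56 (SE 1.53, unadjusted p = 0.00144). The share of all gene counts taken by the shunt list was 0.179% ± 0.109 on OP50 and 0.0413% ± 0.0048 on *Methylobacterium* (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). On the shared stretch it was 0.230% ± 0.146 on OP50 and 0.0487% ± 0.0095 on *Methylobacterium*. The shares of the muscle and cuticle marker lists were lower in the same libraries, as given further on.

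**Figure D2:**
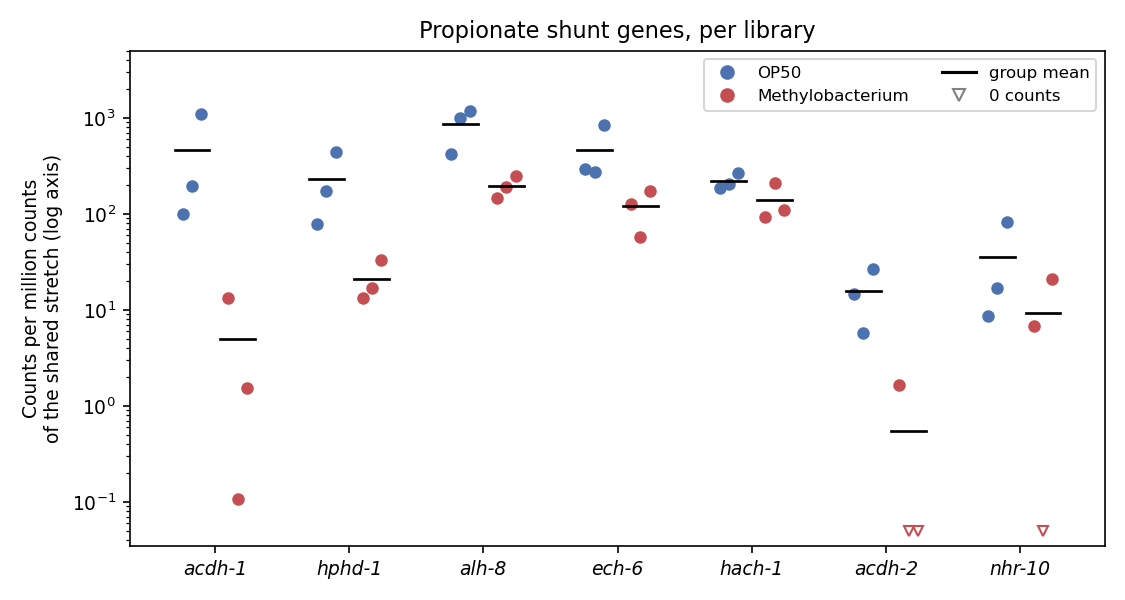
CPM of the shared stretch (log axis) for the 7 members of the propionate shunt list on that stretch, 1 point per library, with OP50 in blue, *Methylobacterium* in red, group means as bars and libraries at 0 counts as open triangles near the axis. The members include the nuclear hormone receptor gene *nhr-10*. The 3 OP50 libraries lie above the 3 *Methylobacterium* libraries for *acdh-1*, with group means of 467 and 4.96, and also for *hphd-1*, *alh-8*, *ech-6* and *acdh-2*.

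The list of lipid breakdown and beta oxidation genes, which shares *acdh-1*, *acdh-2* and *ech-6* with the shunt list, also fell. Its median log2 fold change was -1.11 over 45 genes and -0.93 over the 31 on the shared stretch, with 39 and 27 members negative (camera adjusted p = 0.000607 and 0.000198; adjusted p = 0.812 with an estimated correlation, and 0.497 on the shared stretch). *acs-2* (CELE_F28F8.2, chromosome V, 15567394 to 15569897), an acyl-CoA synthetase that feeds fatty acids into beta oxidation, had 815, 205 and 440 counts on OP50 and none in the 2 *Methylobacterium* libraries that counted its position. Against a floor of 3 counts over those libraries it was at least 1266-fold lower, or 529-fold without OP50 replicate 3, 754-fold without *Methylobacterium* replicate 2 and 513-fold without replicate 3. The last bound rests on replicate 2 alone, which by itself does not show a lower level. *acdh-7*, an acyl-CoA dehydrogenase, had 429, 505 and 179 counts on OP50 and none in replicate 2, the 1 *Methylobacterium* library that counted it, which does not show a lower level. The floor covers counting error only. Of the whole list, 0 genes passed edgeR's test adjusted over all genes. DESeq2 on all genes, where uncounted zeros also enter as measured, called *acs-2* (adjusted p = 8.15e-07) and *acdh-7* (2.31e-06) among others. With edgeR's p-values adjusted over the list alone, *acs-2* and *acdh-7* passed in the fit that takes uncounted zeros as measured, and *acdh-1* on the shared stretch. Without OP50 replicate 3, the shallowest library, the list's call on all genes ended (median -0.91, adjusted p = 0.122). The median was larger without OP50 replicate 1 (-1.81, or -1.45 on the shared stretch), without *Methylobacterium* replicate 3 on all genes (-2.30) and without *Methylobacterium* replicate 1 on the shared stretch (-1.72).

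The lipid binding and transport list, which holds the vitellogenins and fatty acid binding proteins, fell with a median log2 of -1.88 over 38 genes and -1.295 over 18 on the shared stretch (camera adjusted p = 0.0038 and 0.013; adjusted p = 0.812 and 0.497 with an estimated correlation). Its call ended without OP50 replicate 3 (median -1.17, adjusted p = 0.319) and without *Methylobacterium* replicate 1 (-1.315, 0.111) or replicate 3 (-2.065, 0.0587). The same 3 libraries ended it on the shared stretch (medians -0.884, -1.085 and -1.463; adjusted p = 0.289, 0.0693 and 0.0973). The list shares the vitellogenins with the intestine markers, and both varied within OP50. In replicates 1, 2 and 3 it took 0.338%, 0.861% and 1.23% of gene counts and the intestine list 0.0205%, 0.217% and 0.957%, against means of 0.29% and 0.0665% on *Methylobacterium*. These means take in *Methylobacterium* replicate 1, which counted 20 of the 43 lipid binding genes and 7 of the 25 intestine genes. On the shared stretch the intestine list took 0.0211%, 0.107% and 0.415% on OP50 replicates 1, 2 and 3. There it took 0.0865%, 0.0324% and 0.0251% on *Methylobacterium*, with overlap. The canonical propionate and methionine cycle list was called on the shared stretch alone, with a median of -0.71 and 15 of 17 members negative (adjusted p = 0.0353, against 0.179 on all genes; adjusted p = 0.497 with an estimated correlation). That call ended without OP50 replicate 1 (0.0662), 2 (0.0684) or 3 (0.328) or *Methylobacterium* replicate 1 (0.298) or 3 (0.124). Its member *metr-1*, the vitamin B12-dependent methionine synthase, was at 507 ± 444 on OP50 and 172 ± 19.7 on *Methylobacterium* (2.95-fold lower, or 1.46-fold without OP50 replicate 3), whereas *mmcm-1*, the other enzyme that uses the vitamin, was at 99.2 ± 47.2 and 82.6 ± 11.2. The fatty acid desaturase genes *fat-5*, *fat-6* and *fat-7* lay outside the shared stretch. Levels of *fat-6* were 12.05, 60.4 and 288 on OP50 and 0 and 18.7 in the *Methylobacterium* libraries that counted it. Those of *fat-7* were 1.71, 20.7 and 0 against 0 and 0.0362, and those of *fat-5* were 0.301, 6.98 and 2.42 against 0 in both.

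The lists of cuticle and of muscle genes were lower against other genes on *Methylobacterium*. The epidermis and cuticle list, mostly collagens, fell with a median log2 of -2.65 over 160 genes, 146 of them negative, and -2.13 over 89 on the shared stretch (camera adjusted p = 3.21e-10 and 1.62e-08; adjusted p = 0.812 and 0.497 with an estimated correlation). No member passed edgeR's test, over all genes or adjusted over the list alone. DESeq2 on all genes called members outside the shared stretch, such as the collagen *col-175* (adjusted p = 7.86e-05). Its 3 members with the highest mean CPM were collagens whose groups overlapped. On OP50 replicates 1, 2 and 3 *col-125* was at 179, 91.5 and 2840, *col-10* at 35.9, 62.0 and 3099, and *col-144* at 37.2, 92.2 and 2606. On *Methylobacterium* *col-125* was at 78.0, 115 and 298, and in the 2 libraries that counted them *col-10* was at 107 and 220 and *col-144* at 73.9 and 127, so without OP50 replicate 3 the means of all 3 were higher on *Methylobacterium*. All 35 muscle genes were negative, with a median of -1.33, as were all 17 on the shared stretch, also at -1.33 (adjusted p = 0.000295 and 0.000112; adjusted p = 0.812 and 0.497 with an estimated correlation). The muscle gene with the highest mean CPM, the actin *act-4*, was at 2157, 7981 and 4578 on OP50 and 2254 and 2428 in the 2 *Methylobacterium* libraries that counted it (2.095-fold lower, with overlap). The myosin heavy chain *unc-54* was at 3736 ± 966 against 1022 ± 715 (3.66-fold lower, or 6.13-fold without *Methylobacterium* replicate 2) and the tropomyosin *lev-11* at 1998 ± 910 against 734 ± 316 (2.72-fold lower), both without overlap.

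Of the muscle genes, 0 passed edgeR's test over all genes, and 5 of 17 passed it on the shared stretch adjusted over the list alone. OP50 replicate 3 took 3.75% of its counts from the cuticle list, against 0.586% and 0.453% in the other OP50 libraries. Without it the median of the cuticle list was -1.004 (adjusted p = 0.0106), or -0.85 on the shared stretch (0.025), whereas without *Methylobacterium* replicate 3 it was -4.32 on all genes. The muscle call ended without OP50 replicate 3 (median -1.418, adjusted p = 0.155, and -1.07, 0.0776 on the shared stretch), and on all genes without *Methylobacterium* replicate 3 (-1.603, 0.0615). Its median on all genes was -2.06 without *Methylobacterium* replicate 2.

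The list of cytosolic ribosomal protein genes was higher against other genes on *Methylobacterium*. Of 64 genes, 57 had a positive log2 fold change, with a median of 0.52, and on the shared stretch 48 of 49 did, with a median of 0.63 (camera adjusted p = 2.22e-06 and 1.62e-08; adjusted p = 0.812 and 0.497 with an estimated correlation). Levels of *rps-25* were 1005 ± 150 on OP50 and 1930 ± 206 on *Methylobacterium* (1.92-fold higher), and those of *rps-24* were 1431 ± 549 and 3006 ± 303 (2.10-fold higher), both without overlap. The list took 8.61% ± 1.82 of gene counts on OP50 and 12.7% ± 1.67 on *Methylobacterium* (SD, n = 3; exact permutation p = 0.1). No member passed edgeR's test over all genes or adjusted over the list alone. Fry, which tests a list against no change, did not call the ribosomal list (adjusted p = 0.551, and 0.18 on the shared stretch). On all genes the median fell to 0.217 without *Methylobacterium* replicate 3, and over the fits on the shared stretch that left out 1 library it lay between 0.529 and 0.729. The propionate shunt, ribosomal protein and cuticle lists were the 3 that kept their call in all 12 fits that left out 1 library. These fits were on all genes and on the shared stretch. Under the 3 other scalings every called list kept its call. With the libraries grouped otherwise into 3 and 3, camera's unadjusted p for the ribosomal list on the shared stretch was as low as 4.14e-06. The grouping by food gave 1.16e-09, so low values for this list also arose without that grouping.

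Sperm genes, which include the major sperm proteins, fell with a median log2 of -1.499 over 72 genes and -1.53 over 64 on the shared stretch (camera adjusted p = 0.0248 and 7.02e-06; adjusted p = 0.812 and 0.675 with an estimated correlation). OP50 replicate 1 took 0.805% of its counts from this list, against 0.359% and 0.144% in the other OP50 libraries and 0.154% to 0.169% on *Methylobacterium*. Without that library the call ended and the median shrank (-0.825, adjusted p = 0.855, and -0.749, 0.16 on the shared stretch). On all genes it also ended, with the median kept, without OP50 replicate 2 (-1.70, 0.0609) and without *Methylobacterium* replicate 2 (-1.549, 0.0768) or replicate 3 (-1.762, 0.315). The oxidative and xenobiotic stress list fell with medians of -1.55 over 93 genes and -0.67 over 59 (adjusted p = 0.0034 and 0.0243; adjusted p = 0.812 and 0.706 with an estimated correlation). Its call on all genes ended without *Methylobacterium* replicate 2 (median -1.757, adjusted p = 0.0742), and its median was -4.97 without replicate 3. On the shared stretch the call ended without *Methylobacterium* replicate 2 (-0.94, 0.28) or OP50 replicate 2 (-0.0528, 0.115), and the median was -1.416 without OP50 replicate 1 and -1.795 without *Methylobacterium* replicate 3.

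Another 4 lists were called on all genes but not on the shared stretch, and uncounted genes entered those calls. These were the mitochondrially encoded genes (median -3.73 over 12, adjusted p = 2.22e-06, none on the shared stretch), the intestine (-2.96 over 21, adjusted p = 0.0248 against 0.756 on the shared stretch), the innate immune effectors (-1.87 over 95, 0.0248 against 0.0945) and the guanylate cyclases (-2.20 over 13, 0.0328 against 0.0835), each with adjusted p = 0.812 with an estimated correlation. On all genes, the mitochondrial call ended without *Methylobacterium* replicate 3 (median -3.36, adjusted p = 0.0587). The median was -16.8 without replicate 2, where only uncounted zeros were left on *Methylobacterium*. The guanylate cyclase call ended without OP50 replicate 2 (-0.951, 0.235) or *Methylobacterium* replicate 3 (-7.45, 0.219). On the shared stretch this list was called in 4 of the 6 fits that left out 1 library, with medians of -1.67 to -2.85. Leaving out OP50 replicate 2 or 3 or *Methylobacterium* replicate 2 or 3 ended the calls of the intestine (medians -3.02, -1.886, -2.43 and -4.71; adjusted p = 0.116, 0.622, 0.079 and 0.1003). The same 4 libraries ended those of the immune effectors (-1.359, -1.139, -1.504 and -4.17; 0.412, 0.356, 0.629 and 0.14). In the 1 *Methylobacterium* library that counted them, the mitochondrial genes took 0.58% of gene counts, close to the 0.592% of OP50 replicate 1, whereas OP50 replicates 2 and 3 had 1.25% and 3.35%. The vitellogenin *vit-6* on the shared stretch was at 6.63, 503 and 3148 on OP50 and at 420, 161 and 13.7 on *Methylobacterium*.

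**Figure D3:**
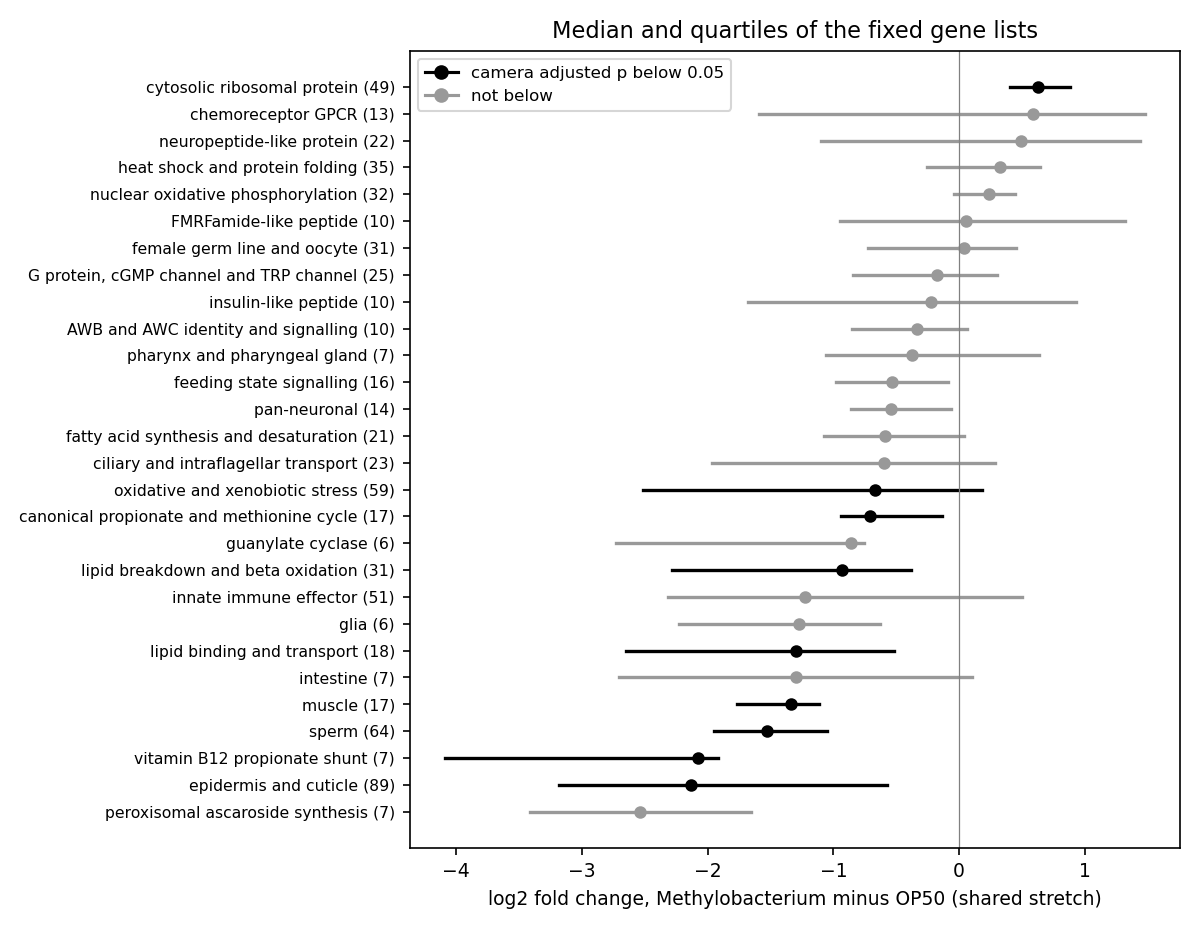
Median (point) and quartiles (line) of the log2 fold change, *Methylobacterium* minus OP50, of the 28 fixed gene lists with enough members on the shared stretch, with the number of genes in brackets. Black lists had a camera adjusted p below 0.05 with the preset correlation and grey ones did not; the ribosomal protein list was at 0.63 and the propionate shunt list at -2.08.

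The gene list for the neurons named in the labels was not called. The list of AWB and AWC identity and signalling genes had a camera adjusted p of 0.451 on all genes and 0.707 on the shared stretch, and took 0.0725% ± 0.0158 of gene counts on OP50 and 0.0557% ± 0.0035 on *Methylobacterium* (SD, n = 3; exact permutation p = 0.2). On the shared stretch, which holds 14 of its 29 genes, the shares were 0.0825% ± 0.0243 and 0.0604% ± 0.0074. Several genes that mark these neurons had few counts, so the absence of a call does not show that expression in AWB and AWC was unchanged. The receptors *str-1*, *str-2* and *srsx-3* were counted in OP50 replicate 2 alone, with 32, 19 and 37 counts, and the channel subunit *tax-4* had 2 counts there and 0 elsewhere. The level of *odr-1*, whose promoter drives the reporter, was 0.753, 179 and 49.5 on OP50 and 18.2 and 3.66 in the *Methylobacterium* libraries that counted it. The transcription factor *ceh-36* had 24, 35 and 0 counts against 0 and 19, the G protein *odr-3* 59, 75 and 1 against 1 and 76, and the channel subunit *tax-2* 42, 36 and 0 against 62, 0 and 16. *lin-15A* and *lin-15B*, the locus used as the rescue marker of the transgene, were at 19.1 and 156, 371 and 807, and 141 and 293 in OP50 replicates 1, 2 and 3, and at 60.6 and 230, and 14.6 and 118.9 in *Methylobacterium* replicates 2 and 3.

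Lists of other neuronal genes were not called either. On all genes, camera gave adjusted p = 0.328 for pan-neuronal genes, 0.385 for other amphid neurons, 0.789 for ciliary transport, 0.219 for chemoreceptors, 0.965 for G proteins with cGMP and TRP channels, 0.591 for FMRFamide-like peptides, 0.306 for neuropeptide-like proteins, 0.919 for insulin-like peptides and 0.25 for feeding state signalling. The remaining lists gave 0.18 for fatty acid synthesis and desaturation, 0.171 for ascaroside synthesis, 0.118 for heat shock and folding, 0.0801 for nuclear oxidative phosphorylation, 0.291 for the female germ line, 0.0611 for glia, 0.23 for coelomocytes and 0.965 for the pharynx. Some were called by camera without *Methylobacterium* replicate 1 and the genes past the end of replicate 3. These were ascaroside synthesis (median log2 -4.10, adjusted p = 0.00601), heat shock and folding (0.206, 0.0159) and nuclear oxidative phosphorylation (0.195, 0.0235). Each had adjusted p = 0.9415 with an estimated correlation. They were not called on the shared stretch (adjusted p = 0.0945, 0.191 and 0.126). Of the 3 members of each cell type list with the highest mean CPM, 3 of 16 counted in all libraries did not overlap between the foods, where chance gives 10% (*unc-54*, *lev-11* and the sperm gene *fer-1*, lower). Of 14 counted in 2 *Methylobacterium* libraries 3 did not, where chance gives 20% (the pan-neuronal *snb-1* and the pharyngeal *phat-4*, higher, and the coelomocyte gene *rme-1*, lower). The germ line and muscle lists each took more counts than the pan-neuronal list in all 6 libraries. Pan-neuronal genes took 0.173% ± 0.0767 of gene counts on OP50 and 0.141% ± 0.0345 on *Methylobacterium*, against 1.24% ± 0.739 and 1.14% ± 0.254 for the female germ line, and 2.10% ± 0.705 and 0.709% ± 0.424 for muscle. Within the shared stretch, pan-neuronal genes took 0.160% ± 0.0829 on OP50 and 0.116% ± 0.0125 on *Methylobacterium*. Muscle genes took 1.28% ± 0.434 and 0.433% ± 0.163 there. On the shared stretch, 8 of 30 lists had shares that did not overlap between the foods, where chance gives 10%, and the smallest Benjamini-Hochberg adjusted value of their permutation tests was 0.375. On all genes 8 of 31 did (0.388), but 1 of these was the mitochondrial list, which was uncounted in 2 *Methylobacterium* libraries.

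At the level of single genes, edgeR's quasi-likelihood test called 0 of 12725 genes higher and 0 lower on *Methylobacterium* (smallest adjusted p = 1.00). At an unadjusted p below 0.05, 28 genes were higher and 227 lower. These 255 of 12725 genes are fewer than the fraction of 0.05 that chance gives. Of the 227 lower genes, 55.1% lay outside the shared stretch, against 34.3% of all genes tested. Uncounted zeros entered there as measured values. DESeq2 called 1 higher and 622 lower. On the shared stretch edgeR called 0 of 8397 genes, and DESeq2 called 6 higher and 207 lower. There 347 genes had an unadjusted p below 0.05 in edgeR's test, also under that fraction, and 224 of them were lower. Of DESeq2's 623 calls on all genes, 412 lay outside the shared stretch and 187 had over 90% of their counts in 1 library. TMM scaling left a median log2 fold change of -0.28 over all genes, against -0.44 with DESeq2's size factors, -0.30 with library totals and -0.18 with upper quartiles, and of -0.03 on the shared stretch.

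As no gene passed edgeR's test, those with its lowest p-values are given as not past its threshold. On the lower side, after *acs-2* (log2 -13.24, unadjusted p = 0.000773) and *acdh-7* (-12.64, 0.00115), these were *osm-11*, which encodes a secreted Notch co-ligand (-11.76, 0.000868; 397, 346 and 1043 counts on OP50 and 2 in the 1 *Methylobacterium* library that counted it), F02H6.2 (-13.05, 0.00108; 751, 151 and 391 counts against 0 in both *Methylobacterium* libraries that counted it) and the collagen *col-175* (-9.82, 0.0015; levels of 188, 78.0 and 57.2 against 0 and 0.29). DESeq2 on all genes called these 5 (adjusted p between 8.15e-07 and 7.86e-05). All 5 lay outside the shared stretch, and their p-values, from edgeR and from DESeq2, come from fits that take uncounted zeros as measured. On the higher side they lay on it: F41G3.10 (3.48, 0.0141; 24.5, 54.1 and 23.8 against 39.1, 196 and 796, with overlap), *rps-25* (1.09, 0.0255), the collagen XVIII gene *cle-1* (2.74, 0.0257; 13.4, 26.8 and 8.45 against 38.2, 55.6 and 202), *rps-24* (1.21, 0.0267) and F33H2.3 (1.595, 0.0268; 68.4 ± 8.85 against 184 ± 72.5). Without *Methylobacterium* replicate 3 the ratio of means fell from 10.08 to 3.45 for F41G3.10 and from 6.07 to 2.89 for *cle-1*.

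Without *Methylobacterium* replicate 1 edgeR called 1 gene higher and 8 lower on all genes, but 0 higher and 0 lower on the shared stretch (smallest adjusted p = 0.0766). At an unadjusted p below 0.05, 128 were higher and 233 lower on that stretch. These 361 of 9358 genes are fewer than the fraction of 0.05 that chance gives. In the fit that also left out the genes past the end of replicate 3, 7 genes were called with edgeR's adjusted p. The lower ones were *acdh-1* (log2 -8.96, adjusted p = 0.0156), *col-38* (-5.05, 0.0156), *acs-2* (-13.20, 0.0363), *icl-1* (-3.81, 0.0363), *col-175* (-9.28, 0.0455) and F02H6.2 (-13.01, 0.0478), and the higher one was F41G3.10 (3.97, 0.0363). *col-38* was at 191 in the library left out, above the 169 of OP50 replicate 2, so its groups overlapped (unadjusted p = 0.151 with all 6 libraries). F41G3.10 overlapped too, at 39.1 in the library left out against 54.1 in OP50 replicate 2. *icl-1*, which encodes the glyoxylate cycle enzymes isocitrate lyase and malate synthase, was at 547 ± 277 on OP50 and 36.4 ± 7.80 in 2 *Methylobacterium* libraries (15.01-fold lower). *icl-1* and *col-38* were named after their values were seen, as were *hphd-1*, *alh-8*, *ech-6*, *acdh-2*, *hach-1*, *metr-1* and *mmcm-1*.

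A search over gene classes, the families of genes that share the letters of their symbol, called 23 of 116 classes, 9 higher and 14 lower on *Methylobacterium*, and 19 of 70 on the shared stretch, 8 higher and 11 lower. Among the higher ones were the mitochondrial ribosomal proteins (*mrpl*, median log2 0.78 over 42 genes, 0.86 on the shared stretch; *mrps*, 0.69 and 0.93) and the translation initiation factors (*eif*, 24 of 25 genes positive, 0.54 and 0.58). RNA polymerase subunits (*rpb*) were positive for all 11 genes, with medians of 0.82 and 0.85. The lower ones included the patched-related genes (*ptr*, -2.37 over 22 genes and -2.42 over 16), the acyl-CoA dehydrogenases (*acdh*, -1.55 and -1.56), the acyl-CoA synthetases (*acs*, -1.72 and -1.07), nuclear hormone receptors (*nhr*, 99 of 124 negative, -1.404 and -1.11) and UDP-glucuronosyltransferases (*ugt*, -2.68 and -2.29). Camera's adjusted p lay between 2.77e-06 and 0.003 for these classes on all genes, and no class was called with an estimated correlation (lowest adjusted p = 0.906 with an estimated correlation, and 0.72 on the shared stretch). Fry called 0 classes on all genes (lowest adjusted p = 0.187) and 1 on the shared stretch, *acs* (0.0111). The *acdh* class holds *acdh-1* and *acdh-2* of the shunt list. On all genes the *acdh* call ended without *Methylobacterium* replicate 3 (median -1.79, adjusted p = 0.192), as did the *acs* call (-2.99, 0.0525). The *nhr* call ended without *Methylobacterium* replicate 1 (-0.917, 0.0977) or replicate 2 (-0.847, 0.187). On the shared stretch, the *nhr* call ended without OP50 replicate 2 (-0.807, 0.0632) or 3 (-0.546, 0.187) or *Methylobacterium* replicate 1 (-1.09, 0.132) or 2 (-0.722, 0.188). There the *acs* call ended without OP50 replicate 1 (-0.777, 0.0688) or 3 (-0.776, 0.148) or *Methylobacterium* replicate 3 (-0.698, 0.168), and the *rpb* call without OP50 replicate 2 (0.802, 0.0632). Each fit was filtered anew, so its medians are not over the same genes. Other medians moved with the call kept. Without *Methylobacterium* replicate 3 those on all genes were -7.16 (*nhr*), -5.47 (*ptr*), -7.23 (*ugt*) and 0.383 (*rpb*), and on the shared stretch -2.29, -3.72 and -5.175 for the first 3. Without OP50 replicate 3 those on all genes were -1.024 (*acdh*), 0.328 (*eif*) and 0.493 (*mrpl*), and on the shared stretch -0.923 (*acdh*), -1.453 (*ptr*) and -1.305 (*ugt*).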

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

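Settings that used the shared stretch, or took uncounted stretches as missing, were chosen after the data were seen. For single genes, edgeR called 0 higher and 0 lower with each scaling, the stricter filter, the robust fit, the shared stretch and uncounted stretches as missing. No filter gave 1 higher and 108 lower, DESeq2 gave 1 and 622, and DESeq2 on the shared stretch gave 6 and 207; the cause was not tested. Fits without 1 library gave 0 to 1 higher and 0 to 8 lower, the highest without *Methylobacterium* replicate 1. The labels do not say whether the replicate numbers pair the samples. Deviations of same-numbered libraries correlated at 0.152, 0.032 and 0.088, and those of other pairs at -0.161 to 0.051, so pairing stays open. With the replicate block 0 genes were called higher and 0 lower, also on the shared stretch, with 11 lists (8 on the shared stretch) and 24 classes (18). On that stretch the smallest adjusted p of edgeR's test was 0.115 with the block and 0.992 without it. With an estimated correlation 0 of the 12 lists and 0 of the 23 classes were called, on all genes and on the shared stretch. No filter called 37 classes. Leave-outs gave 7 to 15 lists, 13 to 33 classes and 8 to 17 separated shares (chance gives 20% with 3 against 2, and 10% with 3 against 3), the 17 without OP50 replicate 1 and 15 without *Methylobacterium* replicate 3.

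Among called lists, camera's direction reversed with no call for the intestine in 3 leave-outs on the shared stretch, where its median stayed negative (-1.42, -0.21 and -0.68; -4.71 to -0.21 over all leave-outs), and for sperm without OP50 replicate 1 (-0.83; -2.01 to -0.75); the cause was not tested. Over all values of the called lists under other settings, 181 of 254 kept direction and side of the threshold and 69 lost the call. Of 403 values of the lists not called on all genes, 31 passed. Ascaroside synthesis and nuclear oxidative phosphorylation passed in 5 settings each. Chemoreceptors passed in 3, with a lowest camera adjusted p of 2.13e-04. Of 446 class values 334 kept both and 112 lost the call, and of 465 single-gene values 432 kept both, 29 passed and 4 reversed, all without OP50 replicate 3 (log2 0.366 for *col-125*, 0.464 on the shared stretch, 1.271 for *col-10* and 0.175 for *col-144*); the cause was not tested. Without *Methylobacterium* replicate 3 these 3 genes were at -3.39, -4.27 and -4.57. By depth, 3 counts stand for the most in OP50 replicate 3, at 0.862 CPM. Low genes were also limited in *Methylobacterium* replicate 2, where 31% of expressed genes were under 1 CPM at 23937002 counts.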

Other observations

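All explanatory tests below were chosen only after the results were seen.

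The share of counts on the X chromosome varied within OP50, at 2.48%, 5.76% and 8.33% in replicates 1, 2 and 3, and was 3.04% and 3.82% in *Methylobacterium* replicates 2 and 3. Female germ line genes, which belong to a tissue where most of X is silent, ran the other way within OP50, at 2.05%, 1.05% and 0.608% of gene counts, and stood at 1.36% and 0.863% in those *Methylobacterium* libraries. Vitellogenins and other intestine genes took 0.0205%, 0.217% and 0.957% of the OP50 libraries and 0.0401% to 0.0865% of the *Methylobacterium* libraries. The 0.0865% is that of *Methylobacterium* replicate 1, which counted 7 of the 25 genes. Within the shared stretch the intestine list took 0.0211% to 0.415% on OP50 and 0.0251% to 0.0865% on *Methylobacterium*. Across 7430 genes of the shared stretch, OP50 replicate 3 had the lowest correlations with the other libraries, at 0.549 to 0.668, while OP50 replicate 1 and *Methylobacterium* replicate 1 reached 0.867, close to the 0.869 of OP50 replicates 1 and 2.

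Levels of *phat-4*, a gene of the pharyngeal gland, were 382.3, 143.5 and 382 CPM of the shared stretch on OP50 and 648 and 2154 in the *Methylobacterium* libraries that counted it, and the 7 of 21 pharynx genes on the shared stretch took 0.0506% ± 0.0386 of its counts on OP50 and 0.0449% ± 0.0259 on *Methylobacterium* (SD, n = 3; exact permutation p = 1). The small nematode-specific *nspc* class fell with a median log2 of -3.41, with all 14 tested members negative (camera adjusted p = 5.23e-06; adjusted p = 0.906 with an estimated correlation), and had too few members on the shared stretch to be tested there. Its member *nspc-10* was at 154.5, 192 and 109 on OP50 and 0.213 and 12.6 in the *Methylobacterium* libraries that counted it.

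The counts of *Methylobacterium* replicates 1 and 3 ended at 1 point each on IV and X. A random loss of genes through low input or depth is argued against by the run of expressed genes past each end. In replicate 1 it held 3481 genes, 99.7% of them at 0, against 4.85% before the end. In replicate 3 it held 50 genes, with 94% at 0, against 1.175% before. Levels under 1 CPM past an end follow from its definition, but the length of the run does not. A candidate explanation is that alignments in chromosome order were not counted to their end: the percentage of counts past the end was 0.000151 in replicate 1, against 21.4 in the lowest OP50 library, and 2.00e-05 against 0.793 in replicate 3. These percentages restate the ends and cannot tell how they arose. Whether an alignment file or the counting stopped early was not tested here, and no biological explanation was tested.

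The lower propionate shunt on *Methylobacterium* was not an effect of the uncounted stretches, since all 7 members were negative where all 6 libraries were counted, with a median of -2.08 (-3.38 without *Methylobacterium* replicate 3; camera adjusted p = 1.08e-05, and 0.497 with an estimated correlation). Less intestine, epidermis and muscle RNA in the *Methylobacterium* samples stays open, because shunt counts over the counts of those 3 lists differed by -0.37 on the log2 scale (SD 0.29) and the groups overlapped. For *acdh-1* alone the same log2 ratio was -7.04, -6.74 and -5.23 on OP50 and -9.01, -16.19 and -11.99 on *Methylobacterium*, so this gene fell further than the tissue lists, which does not settle it for the other members. An effect of the food, such as its vitamin B12, stays open as a hypothesis that these data do not test. With 10 splits of the 6 libraries a share under 0.05 cannot be reached; the absolute median of the list was 3.29 in the real split and at most 2.50 in the others, and on the shared stretch 2.08 and at most 1.74.

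The ribosomal protein list was called higher and the cuticle and muscle lists lower on *Methylobacterium*. The low depth of OP50 replicate 3 is argued against for the ribosomal genes, whose median on the shared stretch without it was 0.56 (adjusted p = 1.83e-09). For muscle it is argued against only as the whole source of the lower median. That median was -1.07 without that library (quartiles -1.36 and -0.43) and -1.33 with it (-1.76 and -1.11). Without it 14 of 17 genes were negative and the call ended (camera adjusted p = 0.0776), so a part in the result stays open. For the cuticle it stays open, because the median shrank from -2.13 to -0.85 without that library (quartiles -1.71 and 0.65; adjusted p = 0.025). More germ line RNA on *Methylobacterium*, as the source of the higher ribosomal list, found no support, since the log2 share of the germ line list differed by 0.0067 (SD 0.59) where a rise of 0.63 was needed. It stays open, because without OP50 replicate 1 the difference was 0.405 (SD 0.423). Less muscle and epidermis RNA in the *Methylobacterium* samples also stays open, since it predicts the lower lists themselves. A response of muscle, cuticle and translation to the food stays open as well, untested.

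With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 is possible for any count of calls. The real split called 0 genes higher and 0 lower and the highest other split 0, so that all 10 splits gave as many. It called 12 lists, with 15 in the highest other split and 3 splits giving as many, and 23 classes, with 36 in the highest other split and 2 splits giving as many. On the shared stretch the real split called 9 lists and 19 classes, against 16 lists and 20 classes in the highest other split.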
